A study of Mus musculus with 2 samples.

How the data were processed

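The data were H3K27ac ChIP-seq peak lists of mouse embryonic forebrain at day 14.5, from 2 biological replicates that the labels describe as pools of 24 and 34 embryos, with library fragments of 300 to 500 bp. In all, 4 peak lists in narrowPeak format on assembly mm10 were used. Per the file headers and the deposited descriptions, the replicate 1 and replicate 2 lists each came from 1 alignment with a control alignment of its own, the pooled list from both alignments and both controls, and the replicated list from those 3 lists, by a rule that is not given in the sources used here. The aligner, the peak caller, its version and its thresholds are not given in the sources used here, and the control libraries were not analysed here. The authors give each peak a signal value, which was read here, from the format and the range of the values, as a linear ratio, the fold enrichment over control. The authors also give each peak a deposited p-value as −log10 p and the position of its summit. The largest p in the lists was 0.00982, so the deposited lists include weak peaks. Values of different lists were not compared with each other, since they depend on depth and on the control used. No read counts are part of a peak list, so depth per sample is unknown, and a difference in the number of peaks cannot be separated from a difference in depth.

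The reference was the mouse genome GRCm38 (mm10) with the GENCODE M21 annotation. Peak coordinates were compared with the chromosome lengths, and no peak ran past a chromosome end. Peaks on unplaced or unlocalised scaffolds (7 in the replicated list, 10 in the pooled and replicate 1 lists and 13 in the replicate 2 list) were left out of all tests. Coordinates are 1-based. Protein-coding transcription starts were those of basic transcripts, 41394 starts in all. After 27 second copies of a symbol were left out there were 21911 protein-coding genes, of which 21824 had such a start. A peak was at a promoter when it overlapped 1000 bp on either side of a start. Other peaks were put in exons, introns or intergenic sequence by the position of their summit relative to coding genes.

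Overlap between lists required at least 1 bp. Shares were set against 100 circular shifts of a list within each chromosome, with a one-sided p whose smallest possible value is 0.00990. Gene lists (17 lists, 284 genes, of which 1, Ahsp, was not found in the annotation) were fixed before the data were examined. They covered pallial, subpallial, progenitor, pan-neuronal, postnatal neuron, diencephalic, midbrain and hindbrain, Hox, macroglial, microglial and myeloid, endothelial, mural and meningeal, choroid plexus and hem, erythroid, liver, muscle and housekeeping genes. Promoter peaks per list were tested against all other coding genes with Fisher's exact test, two-sided. Distal peaks were assigned to the nearest coding start within 100 kb, and the mean per list was compared with 100000 draws of genes from the same of 20 classes of territory size, the territory being the stretch around a gene that is nearest to its starts and within that limit (21809 genes have one). The two-sided p of those draws cannot go below 2.00e-05. Consensus sites (18) were counted on both strands within 250 bp of the summit, against 1 window per peak 2 to 10 kb away, outside every pooled peak and promoter and within the same step of 2 percentage points of GC content, with Fisher's exact test and a 95% interval of the odds ratio. In every family of tests p was adjusted by Benjamini-Hochberg, and 0.05 was the threshold. Intervals of shares are exact (Clopper-Pearson), except the Wilson interval of the share of pooled peaks kept as replicated, and cover counting error only. Densely acetylated regions were made by joining replicated peaks over gaps of at most 12.5 kb and ranking them by the sum of peak length times fold, cut where the scaled curve reaches a slope of 1.

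The rule for named genes, also fixed beforehand, took for each list at most 4 members with the highest fold of a promoter peak and at most 3 without a promoter peak in alphabetical order. It added the 20 genes with most distal peaks, the nearest coding genes of the 10 peaks of highest fold and of the 10 joined regions ranked highest, and, for each replicate, the 5 genes with the highest −log10 p among those with a promoter peak in that replicate alone and none in the replicated list.

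Alternatives fixed before the data were examined were the upper 50% of each list by −log10 p, an overlap of 50% of either or of both peaks, lists cut to equal length, promoters of 500 or 2500 bp, distance limits of 50 or 500 kb, motif windows of 100 bp, controls 10 to 50 kb away, a joining distance of 5 kb, a ranking by length alone, and each per-replicate list in place of the replicated list. One was added after seeing the data, the pooled peaks that overlap a peak of both per-replicate lists. The procedures were tested on simulated data. With peaks placed so that 40.1% overlapped, 40.4% was recovered, and with none placed the overlap was 0.685% (p = 0.158, one-sided permutation test). Random gene lists of 15 genes, each judged singly without adjustment, passed in 4.00% of cases by Fisher's exact test and 2.67% by the distal test. Lists with 95% of genes marked, against 65% of other genes, passed in 88.0% of cases, and lists with 2 or 4 times the distal rate in 46.0% and 98.0%. These lists too were judged without adjustment, so the shares do not show how often the tests adjusted over 17 lists would pass. No consensus site passed between 2 sets of control windows, and a site placed in 10% of 706 windows was recovered at 9.35 percentage points. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9. Signal tracks, alignments and read files were not used here.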

Results

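Chromatin immunoprecipitation and sequencing (ChIP-seq) of histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was carried out on mouse forebrain at embryonic day 14.5. The samples form 1 group of 2 biological replicates. Replicate 1 was a pool of forebrains from 24 embryos and replicate 2 a pool from 34 embryos, both of mixed sex. Each replicate had its own peak list, and 2 further lists covered both replicates. The pooled list came from both alignments together, and the replicated list, which the authors derived from these 3 lists by a rule that is not stated, holds a part of the pooled peaks. A replicated peak here is therefore one that the authors list as such, and not necessarily one with a peak in both per-replicate lists. The replicate 1 list held 57719 peaks, the replicate 2 list 107837, the pooled list 87968 and the replicated list 44007. The replicated peaks had a median length of 563 bp and covered 36.3 Mb, 1.33% of the genome. Peak lists carry no read counts, so the sequencing depth of the samples is unknown here. The signal value of each peak, read here as fold enrichment over control, and its −log10 p are the authors' values and describe peaks only within their own list. With 1 group, the comparisons are between the replicates, between lists of genes, and between peaks and shifted or matched genomic positions. Genes, peaks and sequence windows are not replicates, so the p-values of the gene and sequence tests describe these lists and not the variation between embryos.

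The first comparison asked how far the replicates share acetylated regions. Promoters of 10031 protein-coding genes carried a peak in both per-replicate lists, among them Foxg1, the regulator of telencephalic identity, Sox2 of neural progenitors, Tbr1 of early cortical neurons and Dlx1 of inhibitory neuron precursors. A further 320 genes had a promoter peak in the replicate 1 list alone and 1870 in the replicate 2 list alone. Outside the replicated list, the promoters of replicate 1 alone with the highest −log10 p were those of Slc35g3 (86.1), Bag3 (7.53), Drg2 (7.53), Prorsd1 (7.53) and 1700015G11Rik (6.68). The Slc35g3 value belonged to a peak on chromosome 11 at 69757893 to 69760901 that also lay at the start of Polr2a, the largest subunit of RNA polymerase II. Polr2a itself had promoter peaks in both replicates. For replicate 2 alone the highest were Fam84b (12.2), Rint1 (12.03), Azin2 (11.9), Veph1 (11.4) and Dynlt1f (11.1).

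Of the replicate 1 peaks on chromosomes, 71.4% (41216 of 57709) overlapped a replicate 2 peak by at least 1 bp, against 3.51% ± 0.196 (SD over 100 circular shifts of a list along each chromosome). Of the replicate 2 peaks, 34.3% (36969 of 107824) overlapped a replicate 1 peak, against 1.91% after shifts. Both shares lay above all 100 shifts, with p = 0.00990 in a one-sided permutation test, the smallest value those shifts can give. The shared stretches covered 20.7 Mb, which was 76.7% of the bases of the replicate 1 list and 44.6% of those of the replicate 2 list. Stronger peaks were shared more often than weaker ones, though not in every step. In the strongest 10% of each list by its own −log10 p, 100% of replicate 1 peaks and 99.3% of replicate 2 peaks were shared, and in the weakest 10% 47.7% and 7.56%. The lowest share of replicate 1, 40.2%, was in the part next to the weakest, and in replicate 2 the part ranked 7 (9.49%) lay below that ranked 8 (13.3%). The peaks found in one list alone lay near a gene start less often than the shared ones. Of the 16495 peaks of replicate 1 alone 8.28% were at promoters, against 32.9% of its shared peaks, and of the 70860 peaks of replicate 2 alone 8.57%, against 33.5%. When both peaks of a pair had to be covered by at least 50%, the shares fell to 36.7% and 19.6%. With the replicate 2 list shortened to the strongest peaks at the length of the replicate 1 list, 54.3% of its peaks and 63.9% of the replicate 1 peaks were shared.

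**Figure D1:**
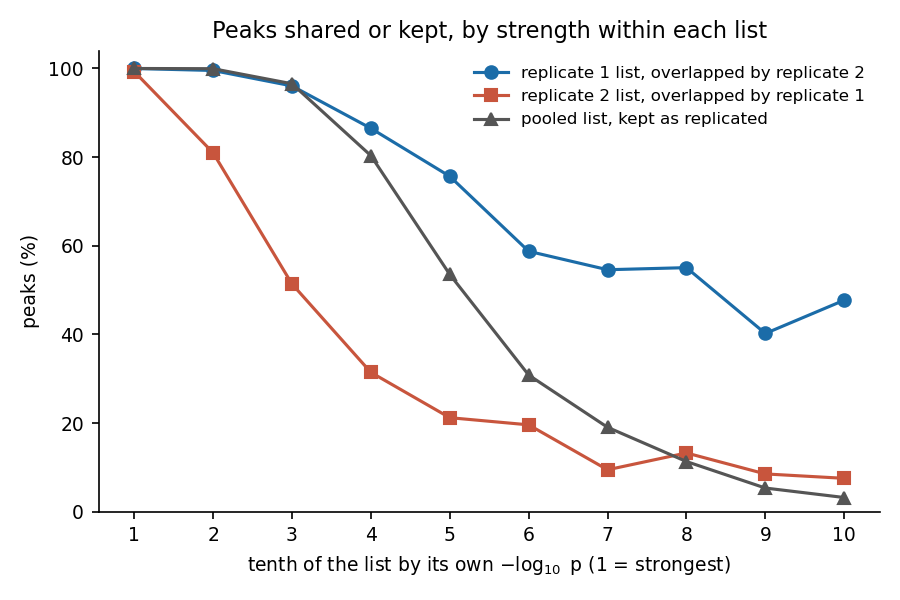
Percentage of peaks (y axis) in each of 10 equal parts of a list ranked by its own −log10 p (x axis, 1 is the strongest) that overlapped the other replicate's list, for replicate 1 (circles) and replicate 2 (squares), or that the authors kept as replicated, for the pooled list (triangles). The strongest parts stood at 100%, 99.3% and 100%, and the weakest at 47.7%, 7.56% and 3.23%.

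The replicated list kept 50.03% of the pooled peaks (44007 of 87968, 95% Wilson interval 49.7 to 50.4, counting error only), each with its start and end unaltered. All of the strongest 10% of pooled peaks and 3.23% of the weakest 10% were kept. Of the replicated peaks, 74.2% overlapped a peak of both per-replicate lists, and 11368 did not. Of the 43961 pooled peaks left out, 54.7% overlapped a peak of replicate 2 alone, 15.4% a peak of replicate 1 alone and 29.0% neither. In the upper 50% of the pooled list by −log10 p the kept share was 86.1%.

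The next comparison located the replicated peaks relative to genes. At promoters, here the stretch within 1 kb of a start of a protein-coding gene, lay 29.6% of the peaks (13006 of 44000 on chromosomes), against 2.93% ± 0.151 (SD) after 100 shifts, which is 10.1 times as many (p = 0.00990, one-sided permutation test, the smallest value possible). Introns held 38.8% against 36.3% ± 0.871 after shifts, and exons 2.73% against 2.42% ± 0.129. Intergenic sequence held 28.9% against 58.4% ± 0.965. Promoter peaks had a median fold enrichment of 7.86, against 4.29 for intronic and 4.52 for intergenic peaks of the same list, and they made up 74.6% of the strongest 10%. The promoter share was 25.9% in the replicate 1 list and 17.1% in the replicate 2 list, and 44.5% among the upper 50% of replicated peaks by −log10 p.

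The peak of highest fold enrichment, 86.1, was intergenic with respect to coding genes. It spanned chromosome 13 from 83713518 to 83734542 (mm10, as are all coordinates here), with its summit 155178 bp from the nearest coding start, that of Mef2c, a transcription factor of neurons and muscle. The start of the long noncoding RNA gene Gm26803 was 1273 bp from its summit. Promoter peaks followed at Sp3 (84.5), which encodes a GC-box binding factor, Klf7 (78.0), a Krüppel-like factor of developing neurons, Zc3h4 (77.1), and Setd1b (74.3), which encodes a histone H3 lysine methyltransferase. Kansl1 (74.0), a subunit of a histone acetyltransferase complex, Nr2f1 (73.6), a regulator of cortical area patterning, Arrdc3 (72.6) and Msi1 (72.6), an RNA-binding protein of neural progenitors, were also among the 10 highest. The Setd1b peak reached the promoter of that gene but had its summit 3275 bp from its start and 13 bp from that of the long noncoding RNA gene 4932422M17Rik. The summit of the Msi1 peak was 6764 bp from the Msi1 start and 281 bp from that of the antisense gene 4930430O22Rik. The remaining one, of 81.0, had its summit 16465 bp from the start of Chd2, a chromatin remodeller, and 33 bp from that of the noncoding transcript 1810026B05Rik.

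Gene lists fixed before the data were examined were then compared with all other protein-coding genes. Of 21824 genes with an annotated start, 10601 (48.6%) had a replicated promoter peak. All 19 genes of the pallial, glutamatergic list carried a promoter peak, with the highest fold enrichment at Foxp1 (44.8), Bcl11b (38.5), which specifies subcortical projection neurons, Fezf2 (30.8), which acts upstream of it, and Tbr1 (30.3). All 19 genes of the radial glia and progenitor list did too, led by Foxg1 (59.3; gene on chromosome 12 at 49382660 to 49386861), Sox2 (45.7), the Notch ligand Dll1 (34.2) and the patterning gene Lhx2 (33.6). So did all 16 pan-neuronal genes, led by the microtubule regulators Stmn1 (35.2) and Map2 (33.6), the neuronal transcription factor Myt1l (29.1) and the tubulin Tubb3 (24.5). Of the 21 subpallial, GABAergic genes, 19 carried a promoter peak. Meis2 (35.0), Gad2 (29.0), an enzyme of GABA synthesis, Dlx6 (28.6) and Dlx1 (27.1) led them, and Gsx1 and Gsx2, progenitor genes of the ganglionic eminences, lacked one. The Gsx2 promoter had a peak in the replicate 1 and pooled lists. Of 15 housekeeping genes 14 carried a promoter peak, with Actb at 69.8, Ywhaz at 63.1, Polr2a at 39.3 and Eef1a1 at 37.2, and Gusb lacked one. These 5 lists lay above the other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjusted p over the 17 lists of 6.19e-06 for the pallial and for the progenitor list, 4.06e-05 for the pan-neuronal, 0.000239 for the subpallial and 0.000805 for the housekeeping list.

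In the replicated list, genes of other body regions and tissues, and those of microglial, myeloid and erythroid cells, were largely unmarked. None of the 39 Hox genes, which pattern the hindbrain and trunk, had a replicated promoter peak (0%, 95% exact interval up to 9.03%, adjusted p = 9.93e-11), and the same held for the 15 liver genes such as Alb, Afp and Ahsg (up to 21.8%, adjusted p = 0.000224) and for the 14 erythroid genes found in the annotation, such as Gata1, Epor and Alas2 (up to 23.2%, adjusted p = 0.000317). Of 15 midbrain and hindbrain genes 1 was marked, Mafb (fold 18.8, adjusted exact p = 0.00196), while En1, Egr2 and Atoh1 were not. Of 14 muscle genes 1 was marked, Myh7 (fold 10.1, adjusted exact p = 0.00298), and of 14 microglial and myeloid genes 1, Csf1r (fold 2.86, adjusted p = 0.00298), the growth factor receptor of macrophages. These 6 lists lay below the other genes by the same test. With the replicate 2 list alone, 28.6% of the microglial and myeloid genes were marked and the list no longer passed, while 20.0% of the midbrain and hindbrain genes were marked and that list still lay below. With the replicate 1 list alone no microglial and myeloid gene was marked, and with the replicate 2 list alone 2.56% of the Hox genes were. Hox genes lie in clusters, so their promoters are not independent of each other. The erythroid regulator Tal1 had a promoter peak in both per-replicate lists and the pooled list, and with either replicate's list alone 7.14% of the erythroid genes were marked.

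The other 6 lists did not pass. Among the postnatal neuron genes 9 of 14 were marked (64.3%, adjusted exact p = 0.345), including Camk2a (13.6), a kinase of excitatory synapses, Kcnc1 (7.38), Bdnf (6.65) and Gabra1 (5.27), and not Cck, Gabra6 or Grin2a. Among the diencephalic genes 8 of 15 were marked (adjusted exact p = 0.799), with Tcf7l2 at 14.8, Lhx9 at 9.33, Barhl2 at 5.71 and Fezf1 at 5.48, and Foxb1, Nkx2-2 and Otp without a peak. The choroid plexus and cortical hem list had 6 of 11 (adjusted exact p = 0.799), among them Otx2 (7.78), Lmx1a (5.95), Foxj1 (5.48) and Wnt8b (3.81), and not Aqp1, Folr1 or Kcne2. Of the endothelial genes 5 of 15 were marked (adjusted exact p = 0.345), among them the glucose transporter Slc2a1 (20.0), Mfsd2a (4.61), Egfl7 (4.29) and Kdr (4.29), and not Cdh5, Cldn5 or Emcn. Of the mural, meningeal and mesenchymal genes 5 of 15 were marked (adjusted exact p = 0.345), among them Foxc1 (5.24), Foxd1 (5.24), Foxf2 (4.76) and Tbx18 (4.29), and not Acta2, Col1a1 or Col1a2. Of the macroglial genes 3 of 12 were marked (adjusted exact p = 0.209), Olig2 (5.24), Gfap (4.02) and Pdgfra (3.57), and Aldh1l1, Aqp4 and Cspg4 were not. Among the upper 50% of replicated peaks by −log10 p the macroglial (8.33%), endothelial (6.67%) and mural (13.3%) lists fell below the other genes and passed. The macroglial list did so too (8.33%) with the pooled peaks over both per-replicate lists, a setting chosen after seeing the data. Some of these unmarked genes had promoter peaks in other lists, Cldn5 in both per-replicate lists and the pooled list, Emcn in the replicate 2 and pooled lists, Cspg4 in the replicate 1 and pooled lists, and Cck, Aldh1l1, Aqp1 and Kcne2 in the replicate 2 list. The endothelial share was 60% with the replicate 2 list alone, and with the replicate 1 list alone the diencephalic share was 46.7% and the choroid plexus share 45.5%, without passing.

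**Figure D2:**
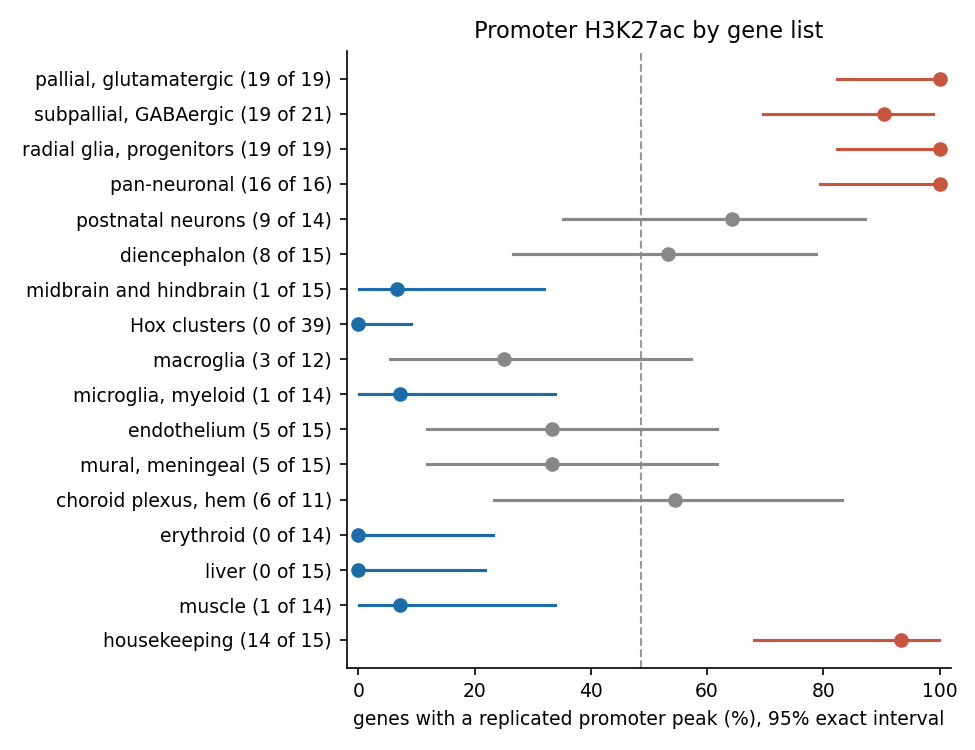
Percentage of the genes of each list with a replicated peak within 1 kb of a start (x axis; points, with 95% exact intervals as bars), beside the share of all protein-coding genes, 48.6% (dashed line). Lists above the line after adjustment are red, lists below it blue and those that did not pass grey, and the numbers beside each name are the marked and annotated genes.

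Distal peaks, over 1 kb from every coding start, were assigned to the nearest coding start within 100 kb. There were 30994 of them, and 73.9% (22919) found a gene. Of the 17 lists, 4 passed, all above matched genes. Pallial genes had a mean of 10.5 distal peaks, against 2.34 for random genes of the same territory size, which is 4.48 times as many (p = 2.00e-05, the smallest the draws can give, adjusted p = 0.000340, two-sided permutation test with 100000 draws, Benjamini-Hochberg over 17 lists). All 19 had at least 1, with 33 at Bcl11b, 21 at Foxp1, 9 at Fezf2 and 7 at Tbr1. Radial glia and progenitor genes had a mean of 6.95 against 1.78 (3.91 times, adjusted permutation p = 0.00193), with 19 at Sox2 and 12 at Lhx2. Subpallial genes had 7.71 against 2.11 (3.65 times, adjusted permutation p = 0.00193), with 21 at Meis2, 10 at Dlx6 and 8 at Dlx1, and pan-neuronal genes 7.63 against 2.32 (3.29 times, adjusted p = 0.0127), with 26 at Myt1l, 17 at Map2 and 1 at Tubb3. In these lists 20 of 21, 17 of 19 and 13 of 16 subpallial, progenitor and pan-neuronal genes had a distal peak. A single distal peak was assigned to Foxg1, since an annotated coding gene that overlaps it, Gm43517, took 14. The means and counts depend on the list. With the list of replicate 1 or of replicate 2 alone, pallial genes had means of 15.3 and 23.7, against 3.18 and 6.64. Progenitor genes then had 9.84 and 15.1, against 2.45 and 5.07. Bcl11b had 49 and 66 distal peaks, Foxp1 28 and 55, and Sox2 35 and 34. All 4 lists passed with either list.

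The other 13 lists did not pass this test. The diencephalic genes had 4.07 distal peaks against 2.24 in matched genes (adjusted permutation p = 0.292) and the housekeeping genes 1.47 against 0.587 (adjusted p = 0.292). The Hox genes had 0.0513 against 0.301 (adjusted permutation p = 0.192), and all of their 2 distal peaks were assigned to Hoxa1. With the list of replicate 1 or of replicate 2 alone the Hox genes passed, at 0.111 and 0.222 times the matched mean. The ratio to matched genes was 0.909 for the postnatal neuron genes, 0.488 for the midbrain and hindbrain, 1.305 for the macroglial, 0.921 for the microglial and myeloid and 0.905 for the endothelial genes. It was 0.343 for the mural, 1.17 for the choroid plexus, 0.605 for the erythroid, 0.329 for the liver and 0.807 for the muscle genes, with adjusted p from 0.292 to 1. With the replicate 2 list alone the ratio of the postnatal neuron genes was 1.09 and that of the endothelial genes 1.14, and with the replicate 1 list alone that of the microglial and myeloid genes was 1.04, none of which passed. The mural ratio was 0.591 and the liver ratio 0.515 with the replicate 2 list alone, and the erythroid ratio 0.311 with the replicate 1 list alone, also without passing.

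**Figure D3:**
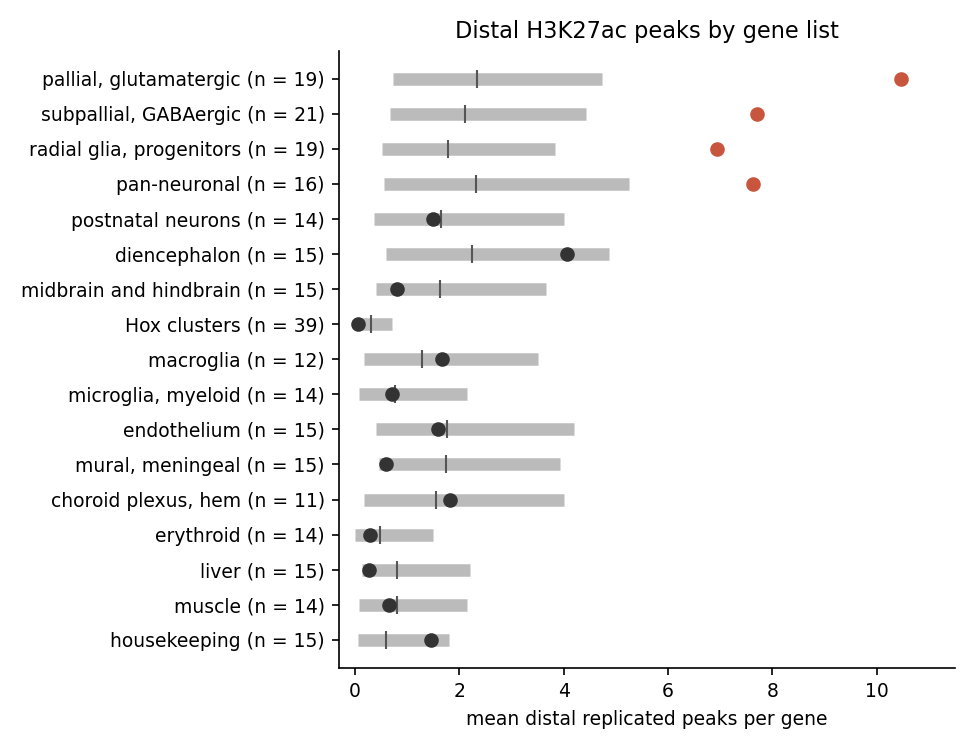
Mean number of distal replicated peaks per gene (x axis) for each list (points, red where the list passed after adjustment), beside the mean (tick) and the central 95% range (grey bar) of 100000 draws of genes matched on territory size. The pallial, subpallial, progenitor and pan-neuronal lists lay between 6.95 and 10.5 peaks, to the right of their ranges.

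The gene with most distal peaks was Tcf4, a transcription factor of neuronal development mutated in Pitt-Hopkins syndrome in people, with 65. Gse1 followed with 56, the transcription factor Bach2 with 55 and Auts2, a gene linked to autism, with 49. Frmd4a had 45, the corepressor Ncor2 44, the Src-family kinase Fyn 40, and Cstad and the RNA-binding protein gene Celf2 35 each. Trak1, Rbfox3, which encodes the neuronal nuclear antigen NeuN, and Prex1 had 34 each, Zmiz1 and Bcl11b 33 each, Gm26897 and Nfib, a nuclear factor of glial and neuronal maturation, 32 each, and Tiam2 31. Chd2, the zinc finger gene Zbtb20 and Vrk1 closed the 20 with 30 each. These counts depend on the list, and with the list of replicate 1 or of replicate 2 alone Tcf4 had 82 and 128, Gse1 81 and 109, Bach2 68 and 117, and Frmd4a 42 and 101, so the order after Tcf4, first in both, is not fixed. The ranking was also not matched on territory size. Territories were 468 kb for Tcf4, 724 kb for Auts2, 640 kb for Frmd4a and 760 kb for Celf2, against 175 kb for Gse1 and 160 kb for Cstad. Of these 20 genes only Gm26897 lacked a replicated promoter peak.

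Short consensus sequences of transcription factor families were then counted in windows of 250 bp on either side of the summits of distal peaks, against windows of matched GC content 2 to 10 kb away and outside all pooled peaks and promoters. Matched windows were found for 25185 of the 30994 distal peaks. Of 18 sites, 10 were more frequent and 4 less frequent in peaks. The homeodomain core shared by LHX, DLX and EMX factors occurred in 14.3% of peaks and 9.10% of controls (odds ratio 1.67, 95% interval 1.58 to 1.76, Fisher's exact test, adjusted p = 1.55e-73 over 18 sites). The SOX site occurred in 59.15% and 49.99% (odds ratio 1.45, 1.40 to 1.501, adjusted exact p = 1.71e-93), the POU octamer in 4.05% and 2.40% (1.71, 1.55 to 1.90, adjusted p = 4.08e-25) and the palindromic E-box of basic helix-loop-helix factors in 32.7% and 26.0% (1.38, 1.33 to 1.44, adjusted p = 3.17e-60). The MEF2 site stood at 1.14% and 0.754% (1.52, 1.27 to 1.83, adjusted exact p = 1.99e-05). Rarer or smaller excesses were found for the RFX site (0.572% and 0.0874%, odds ratio 6.45, adjusted exact p = 1.13e-22), the full NFI site (0.111% and 0.0437%, 2.48, adjusted p = 0.0121), CTCF (1.46, adjusted p = 0.00851), SP/KLF (1.27, adjusted p = 0.000527) and the proneural E-box (1.19, adjusted p = 6.60e-21).

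Sites of the T-box family (odds ratio 0.789, adjusted exact p = 0.000122), the liver factor HNF4 (0.734, adjusted p = 0.00695), the myeloid factor PU.1 (0.862, adjusted p = 0.00388) and AP-1 (0.892, adjusted p = 0.000818) were less frequent in peaks than in controls. Those of NR2F (0.718, adjusted exact p = 0.275), CRE (1.05, adjusted p = 0.832) and the blood GATA factors (0.910, adjusted p = 0.169) did not pass, and the HNF1 site occurred in 1 peak window and no control window. In windows of 100 bp on either side, the SP/KLF (0.693) and CTCF (0.505) sites became less frequent in peaks than in controls, the CRE (0.567) and NR2F (0.422) sites passed as less frequent in peaks, the NFI site stood at 0.556, and the RFX (1.82) and proneural sites (1.01) no longer passed. The HNF4 site passed under no alternative tried. Around the upper 50% of replicated peaks by −log10 p the PU.1 (0.887), SP/KLF (1.18) and NFI (2.64) sites no longer passed. With controls 10 to 50 kb away the CTCF site stood at 1.01 without passing and the RFX odds ratio at 3.35. With the replicate 2 list alone the RFX odds ratio was 3.82, the CTCF site no longer passed (1.11) and the NR2F site passed as less frequent in peaks (0.673).

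**Figure D4:**
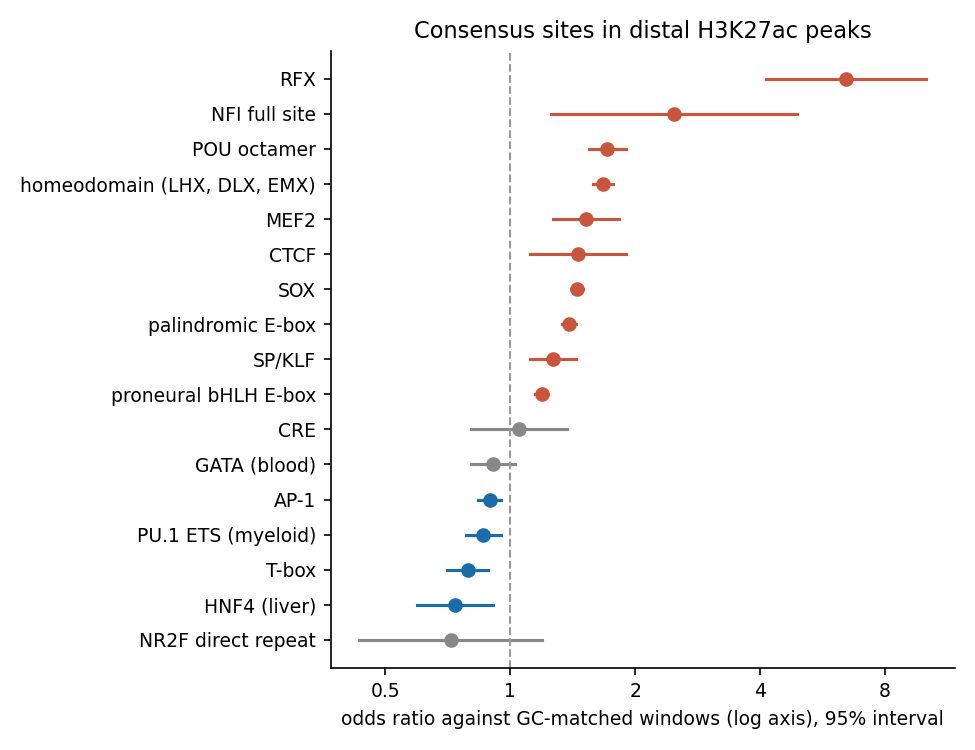
Odds ratio (x axis, log scale) of each consensus site in windows around the summits of distal replicated peaks against GC-matched control windows (points, with 95% intervals as bars). Sites more frequent in peaks after adjustment are red, less frequent blue and those that did not pass grey, the dashed line marks 1, and the HNF1 site, present in 1 window, is not drawn.

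Replicated peaks close to each other were joined, to list the most densely acetylated loci. The joined regions were ranked by the sum over peaks of length times fold enrichment. Promoter peaks were included, and the single fold value of a peak was counted over its whole length, so long peaks weigh heavily. Of 20501 regions, 568 (2.77%) lay above the point where the ranked curve turns. They held 11.8% of the peaks and 32.8% of the summed length times fold, with a median length of 25.2 kb and a median of 7 peaks. They overlapped 11 of the 19 pallial, 11 of the 21 subpallial and 11 of the 19 progenitor genes. They also overlapped 3 of 16 pan-neuronal, 4 of 15 housekeeping and 1 of 15 diencephalic genes, and no gene of the other 11 lists. These counts were not set against the share of all coding genes, matched on gene length or tested. The regions were made from the same replicated peaks as the comparisons above, so the counts are not separate evidence.

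The region ranked first spanned chromosome 7 from 79495626 to 79558015 and held 7 peaks. The coding start nearest to its midpoint, that of the mitochondrial DNA polymerase Polg, was 60459 bp from that midpoint, and the microRNA gene Mir9-3 lay inside it. The second spanned chromosome 13 from 83712735 to 83751227, held 10 peaks including the one of highest fold, and contained Mir9-2. The fifth, on chromosome 3 from 88196835 to 88243674 with Rhbg as the coding gene nearest to its midpoint, contained Mir9-1. These microRNA genes, which encode the neural microRNA miR-9, were outside the rule for named genes and were chosen after their values were seen. The third region covered 326.7 kb over Gse1 with 100 peaks, and the fourth 179.9 kb with 53 peaks around Ntmt1 and 1700001O22Rik. The regions ranked 6 to 10 had, nearest to their midpoints, the coding genes Nfix, a nuclear factor of neural progenitors, Gm43517, which overlaps Foxg1, Nr2f1, Tnrc18 and Sox2.

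**Figure D5:**
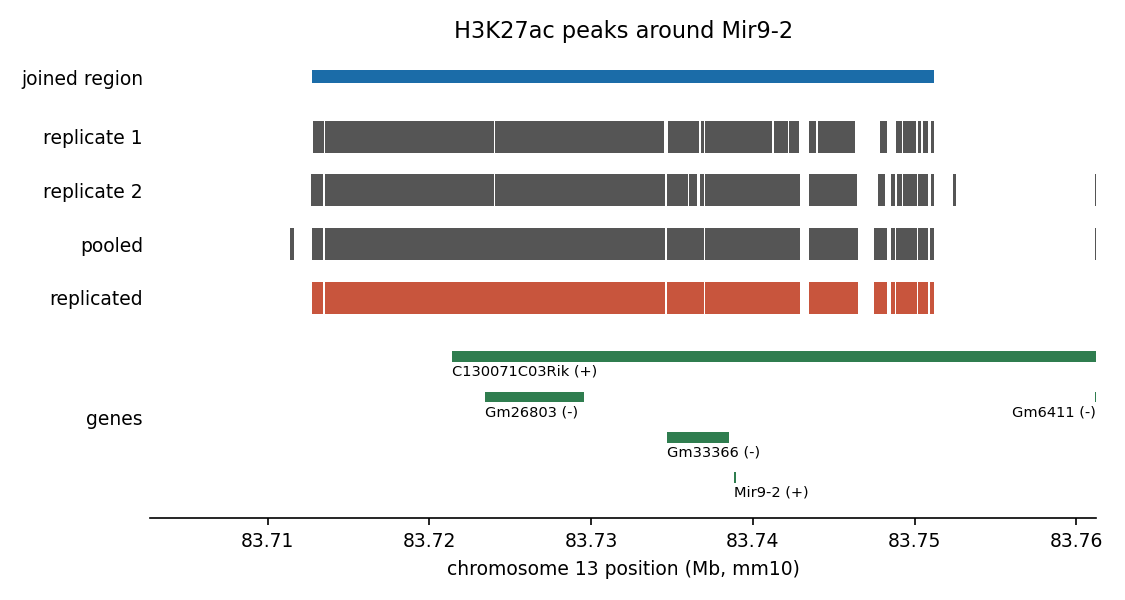
Map of the joined region ranked second, on chromosome 13 (x axis, position in Mb, mm10), with the joined region (blue), the peaks of the 4 lists (grey, replicated in red) and annotated genes of all types with their strand (green). Replicate 1 had 16 and replicate 2 had 14 peaks in the region, and the pooled and replicated lists 10 each.

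Peak density differed between chromosomes. The autosomes carried 17.5 replicated peaks per Mb, from 12.8 on chromosome 3 to 26.3 on chromosome 11, and 2.08 per protein-coding gene, from 1.35 on chromosome 7 to 3.48 on chromosome 12. The X chromosome carried 804 peaks, 4.70 per Mb and 0.848 per gene, below the range of the 19 autosomes on both scales. The Y chromosome carried 1 peak. Both pools held embryos of both sexes, and no test was made of these differences.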

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

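Peaks on unplaced or unlocalised scaffolds stood outside every comparison. The replicated list held 7 of them, above the limit of 3 that a count of 0 allows, and the one of highest fold enrichment (54.0) was 1900 bp long, on a scaffold assigned to chromosome 4 without a position.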

How the results depend on the processing

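Of 332 alternative values, 284 kept their direction and their side of the threshold or stayed within the allowed range. Of the 38 that concern the main shares and counts, 37 did. A share set against shifts had only to stay above them and pass, so this tally does not show stable values. The share of replicate 1 peaks overlapped fell from 71.4% to 36.7% when both peaks had to be covered by at least 50%. The promoter share, 29.6% in the main setting, was 17.1% with the replicate 2 list and 44.5% in the upper 50% of replicated peaks. All of these alternatives are among the 37. The exception was the share of pooled peaks kept as replicated, which was not set against shifts. It rose from 50.03% to 86.1% in the upper 50% of the list by −log10 p. That choice removes weak peaks, which were seldom kept. The counts of lists that passed ranged from 10 to 14 at promoters (main 11) and from 4 to 5 for distal peaks (main 4), the count of consensus sites from 10 to 14 (main 14) and the count of dense regions from 419 to 747 (main 568). The pallial, subpallial, progenitor and pan-neuronal lists stayed above the background under all 6 alternatives for promoters and all 6 for distal peaks, and the homeodomain, SOX, POU, palindromic E-box and MEF2 sites under all 5 for motifs. In windows of 100 bp the odds ratio was smaller than in the main windows for the homeodomain (1.37), SOX (1.36), POU (1.24) and palindromic E-box sites (1.14). For MEF2 it was larger (1.68). The reversals below had causes that were not tested, and most concern lists or sites that did not pass in either setting. Among the upper 50% of replicated peaks the promoter share fell below the background for postnatal neuron (35.7%), diencephalic (26.7%) and choroid plexus genes (27.3%), the distal ratio below 1 for macroglial (0.820) and choroid plexus genes (0.731), and the odds ratio below 1 for CRE (0.955) and HNF1 (0.19996). With promoters of 500 bp the choroid plexus share was 36.4%, and with the pooled peaks over both per-replicate lists, chosen after seeing the data, the postnatal neuron share was 42.9%. With a limit of 50 kb the distal ratio was 0.991 for macroglial, 1.18 for microglial and 1.08 for endothelial genes, and with 500 kb 1.46 for microglial genes. With 1 replicate's list in place of the replicated list, the promoter share ranged from 40% to 60% for endothelial, from 46.7% to 66.7% for diencephalic and from 45.5% to 63.6% for choroid plexus genes, and the distal ratio from 0.718 to 1.09 for postnatal neuron, from 0.715 to 1.14 for endothelial and from 0.828 to 1.04 for microglial genes. With windows of 100 bp the odds ratio was 0.567 for CRE, 0.556 for NFI, 0.693 for SP/KLF, 0.505 for CTCF and 1.07 for GATA, with CRE, SP/KLF and CTCF passing as less frequent in peaks, and with controls 10 to 50 kb away 0.958 for CRE and 1.02 for GATA. No paired analysis was possible because there is 1 group. The unknown depth limits what absence of a peak means. In the simulated lists a doubling of distal peaks was called in 46.0% of cases, each list being judged singly, without the adjustment over 17 lists. Adjustment can only lower that share, so a list that did not pass may still hold a doubling. Whether the simulated counts vary between genes as the real ones do was not tested. The housekeeping genes, at 2.50 times the matched mean, did not pass (adjusted permutation p = 0.292).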

Other observations

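Gene families and gene types outside the fixed lists were tabulated after the data were seen, with families taken as coding genes whose symbols share a stem and of at least 15 members. Of 141 such families, 56 lay above and 43 below the other genes in the share with a replicated promoter peak (Fisher's exact test, two-sided, Benjamini-Hochberg over 141). None of 1133 olfactory receptor genes (Olfr, 95% exact interval up to 0.325%), 22 clustered protocadherins of the beta group (Pcdhb, up to 15.4%, adjusted p = 3.31e-06) and 26 kallikreins (Klk, up to 13.2%, adjusted p = 3.10e-07) was marked, and of 330 vomeronasal receptor genes (Vmn) 1 was. Marked shares were 90.9% of 44 small-subunit ribosomal protein genes (Rps, adjusted exact p = 5.22e-08), 86.6% of 67 histone genes (Hist, adjusted p = 1.64e-09) and 94.4% of 18 histone lysine demethylase genes (Kdm, adjusted p = 0.000181). Members of such families often lie in clusters and are not independent. In distal peaks 2 families lay above and 12 below genes of matched territory (permutation test with 10000 draws), among the latter Olfr with 0.0229 peaks per gene against 0.385 and Vmn with 0.00303 against 0.965. The families above were Sox, with 6.58 peaks per gene against 1.85 (adjusted permutation p = 0.0141), and Bcl, with 4.08 against 1.19 (adjusted p = 0.0152). Sox2, Sox5, Sox9, Sox10, Sox17 and Sox18 of the first and Bcl11b of the second also belong to the fixed lists. In the Bcl family, Bcl11a with 24 and Bcl11b with 33 held over 50% of its 98 distal peaks.

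All 3 genes for miR-9 lay in the 5 joined regions ranked highest (Mir9-3 in the first, Mir9-2 in the second and Mir9-1 in the fifth). The 3 genes for miR-124, a microRNA of neurons, lay in the dense regions ranked 19 (Mir124a-1), 51 (Mir124a-2) and 154 (Mir124a-3). Of all 2202 annotated microRNA genes 90 (4.09%) lay in a dense region, and the dense regions covered 0.660% of the genome. These genes were picked after the top regions had been inspected, so no test was made. Among noncoding genes whose starts all lie over 5 kb from every coding start, 10.1% of 5213 lincRNA genes and 0.871% of 9182 processed pseudogenes had a replicated peak within 1 kb of a start.

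The tests that follow were written down before their results were seen, except the comparison of the remaining stronger replicate 2 peaks and that of 4 lists by CpG class, both chosen afterwards. The comparisons within the highest 2 CpG classes were not among the tests written down. The replicate 2 list was 1.87 times as long as the replicate 1 list, and of its strongest 10%, 0.686% lacked a replicate 1 peak, under the 5% set beforehand for extra peaks that lie near the calling threshold. Of the rest of its upper 50%, however, 53.7% lacked one, so the extra peaks are not limited to the weakest. The largest p was similar in both lists, 0.00876 in replicate 1 and 0.00981 in replicate 2. That argues against a laxer cutoff on p for replicate 2. Other calling settings are not given and depth is unknown, so a difference in either stays open. Cells of another type in replicate 2 stay open too, since distal peaks of replicate 2 alone had a nearest gene in the microglial, endothelial, mural, erythroid, liver or muscle lists in 0.335% of cases (158 of 47216), against 0.323% (36 of 11135) for replicate 1 alone, an odds ratio of 1.04 with a 95% interval from 0.720 to 1.49. Beyond that, no biological explanation was tested, since the design has 1 group.

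The 6 lists below the background at promoters could owe their position to promoters poor in CpG, since 90.7% of other genes in the highest of 5 classes of promoter CpG ratio were marked and 2.05% in the lowest. Within those classes the odds ratio of the 111 genes of the 6 lists together against other genes was 0.0460 (Mantel-Haenszel, 95% interval 0.0153 to 0.138). The 6 lists were picked by these same promoter marks, which tends to lower that odds ratio. In the highest 2 classes none of 21 Hox genes was marked, against 85.0% of other genes, and 1 of 10 midbrain and hindbrain genes. For these 2 lists that argues against CpG content as the whole cause. The liver, erythroid, microglial and muscle lists have 3 of their 57 genes in the highest 2 classes. Together they had 2 marked genes against 8.37 from the shares of other genes in their classes (odds ratio 0.235, 95% interval 0.0648 to 0.852). Since these lists too were picked by the same marks, that value cannot decide the question. Both marked genes were in the lowest class, where the 4 lists were marked more often than other genes (8.70% against 2.05%). For these 4 lists, together and alone, CpG content stays open. For the 5 lists above the background, CpG content was examined in the highest 2 classes only. In the highest 2 classes 84.8% of other genes were marked, so the gap was smaller there than over all genes. All 10 pallial, 11 progenitor, 9 pan-neuronal and 10 housekeeping genes in those classes were marked, and 12 of 13 subpallial genes. None of the 5 lists passed there (Fisher's exact test, two-sided, unadjusted p from 0.372 to 0.706). With 9 to 13 genes per list and 84.8% of other genes marked, that test cannot decide the question. CpG content therefore stays open for these lists. Their genes in the other classes were not compared. No biological explanation was tested.

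The 4 lists above matched genes in distal peaks might share that excess with any gene that has a promoter peak. The 75 genes had a mean of 8.20 distal peaks, against 3.09 (95% range of draws 2.05 to 4.36) in matched genes drawn only from those with a promoter peak, which Gsx1 and Gsx2 among the 75 lack, a ratio of 2.65 (permutation test, p = 2.00e-05, the smallest the draws can give). These 75 genes thus had more distal peaks than matched genes with a marked promoter. The 4 lists were picked by the same counts, however, which tends to raise that ratio, and the p-value does not allow for it. The comparison therefore cannot decide whether a marked promoter is the whole cause. The assignment of a distal peak to the nearest start was not checked against contacts or expression, and no biological explanation was tested.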
